A study of Caenorhabditis elegans with 2 samples.

How the data were processed

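Chromatin immunoprecipitation was performed with an antibody against green fluorescent protein on early embryos of a worm strain that expresses tagged HMG-4, with 2 biological replicates in 1 group. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and the embryos were at 0 hours. No sequencing depth was given in the sources used here, and peak lists do not hold it, so the depth and the precision it gives are unknown. Control libraries were not used here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here.

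The authors deposited 4 peak lists on the ce11 build: one per replicate, one called on both replicates pooled, and one thresholded by the irreproducible discovery rate. Per the file headers of the accompanying text files, the lists were derived from alignments together with a control alignment, which was the same for both replicates. The signal value of each peak is the deposited enrichment measure of the authors' caller. It was about additive, in that the pooled value over the sum of both replicates' values had a median of 0.998 over IDR peaks (5th to 95th percentile 0.821 to 1.07). Values were compared within a list by rank and median, and between lists by correlation, ratio and difference. Between lists, a peak was matched to the strongest overlapping peak of the other list, so neighbouring peaks can share 1 matched value. The deposited −log10 q-value column was read but not used to choose peaks. The p-value column holds -1 throughout. Each of the replicate and pooled lists ends at exactly 30000 peaks, so a list's weakest peaks depend on that limit. The IDR list was identical to the 2137 strongest pooled peaks by signal value (2137 of 2137, lowest value 130), and 11 IDR entries repeat an interval with another summit. No interval and signal value was shared between the replicates' lists (0 peaks), so they were kept as separate samples.

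Positions were set against the genome of the same build, whose 6 nuclear chromosomes total 100 Mb and contain every peak, and Ensembl release 115 gene annotation with 46890 nuclear genes, of which 19973 are protein-coding. RNA genes that carry only an identifier there were named through the RefSeq annotation where it pairs them. Coordinates are 1-based. Summits were assigned to 7 classes in order of priority: within 500 bp of a gene's 5' end, coding exon, UTR exon, non-coding RNA exon, intron, within 500 bp downstream, and intergenic. Expected values came from 1000 circular shifts of all summits within chromosomes, which keep the clustering of peaks and genes; the smallest p they can give is 0.001 one-sided and 0.002 two-sided. The overlap of replicates used the 2137 strongest peaks of each. Gene lists were tested with two-sided Fisher's exact tests, protein-coding lists against the other protein-coding genes and RNA classes against all other annotated genes, with Benjamini-Hochberg adjustment over 32 lists and a threshold of 0.05. Chromosomes were tested with exact binomial tests against length, adjusted over 6. Peak strength was tested with 100000 permutations. Peaks, genes and shifts describe these lists, and no p measures the spread between cultures, since only 2 replicates exist.

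The lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from the alternatives and tests named below as chosen afterwards. The rule names the genes with a 5' end within 500 bp of the summits of the 25 strongest IDR peaks (otherwise the gene that holds the summit or the nearest), up to 4 members with the strongest peak of each list past the threshold, hmg-3, hmg-4, spt-16 and unc-119, and the genes at up to 5 peaks per replicate among its 2137 strongest that overlap no peak of the other. Genes named for lists that did not pass, and the neighbours of hmg-4, were chosen after their values were seen. A gene that the rule names is not reported here. The list called chemoreceptors was selected by a symbol pattern that also matched 55 genes outside the chemoreceptor families, out of 1364.

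Alternatives varied the overlap criterion (50% reciprocal, or summits within 100 bp), the number of peaks, the promoter window (200 or 1000 bp), the summit or midpoint, the expected share per chromosome, peaks merged within 10 kb, genes merged within 2 kb, circular shifts in place of Fisher's test, the GC window (400 bp), the window around loci (10 or 50 kb) and each replicate left out in turn, where the 2137 strongest peaks of the other replicate took the place of the IDR list. The gene-list, class and overlap functions were tested on simulated data. In 100 simulated sets with no effect, 5% gave any call among 23 protein-coding lists. These sets marked genes at random, so they held no clustered genes or shared peaks, and they did not cover the RNA lists. A list of 200 genes with peaks added at 5% of its members on top of shifted peaks was called in 95% of 100 sets, and at 10% in 100% of sets. That list was larger than most protein-coding lists, and shifted peaks lie at fewer gene starts than the real ones. The shares called therefore do not give the power for the real lists. Of 100 shifted peak sets, 4% gave a promoter p under 0.05. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.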

Results

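HMG-4 is a worm homolog of the SSRP1 subunit of FACT, a histone chaperone that travels with RNA polymerase. Sites recovered with tagged HMG-4 were mapped in early embryos of Caenorhabditis elegans by chromatin immunoprecipitation and sequencing. The worms carried a transgene that makes HMG-4 with a green fluorescent protein and FLAG tag at its C-terminal end, and chromatin sheared to 200 to 800 bp was precipitated with an antibody against the fluorescent protein. Embryos were collected at 0 hours by bleaching of egg-bearing adults. There was 1 group, with 2 biological replicates, and no group to compare it with, so the comparisons are between the replicates and between places in the genome. The values are peaks, that is, stretches of the ce11 genome where the authors' caller found more reads than in a control. Each replicate's list held exactly 30000 peaks, as did the list called on both replicates pooled, and the authors' list thresholded by the irreproducible discovery rate (IDR) held 2137. The 2137 IDR peaks covered 850 kb, or 0.848% of the 6 nuclear chromosomes, with a median width of 440 bp, whereas the 30000 pooled peaks covered 12.2 Mb, or 12.2%. The lowest deposited −log10 q-value was 0.361 in replicate 1's list, 0.0743 in replicate 2's and 0.281 in the pooled list, against 2.47 in the IDR list. The lists of 30000 therefore include weak entries without significant enrichment, and values taken over full lists include these entries. The read depth behind the lists is unknown, so no precision could be derived from it, and confidence intervals below are exact binomial intervals (95%) that cover counting error over peaks or genes only. Peak strength is the authors' signal value, which was used to rank peaks within a list.

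The question of how well the replicates matched comes first. Of the 2137 strongest peaks of replicate 1, 1244 (58.2%) overlapped one of the 2137 strongest of replicate 2 by at least 1 bp, and 1275 (59.7%) of those of replicate 2 overlapped one of replicate 1. Shifting the peaks of 1 replicate along the chromosomes 1000 times gave a mean overlap of 1.87% and a maximum of 2.95% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Overlap was highest among the strongest peaks, at 70.0% for the top 100, fell to 49.5% for the top 5000 and 46.01% for the top 10000, and rose again to 55.8% over all 30000. Overlap by chance grows with the number of peaks, as each replicate's 30000 peaks covered 12.1% of the genome. The shifted mean above holds for 2137 peaks only, so these shares do not have the same chance level. Of the IDR peaks, 1938 (90.7%) had a peak in both replicates' own lists. Over these, the signal values correlated with a Pearson r of 0.849 and a Spearman rho of 0.571. This correlation is across peaks, which are not independent replicates and which were selected by their pooled signal value. Each IDR peak took the value of the strongest overlapping peak in each replicate's list, so some IDR peaks carried the same values. One such shared pair was 509 in replicate 1 and 607 in replicate 2. Weaker IDR peaks can thus carry a stronger neighbour's values, and these were counted more than once in the correlation. The median ratio of the replicate 1 to the replicate 2 value was 1.22, and 5% of peaks lay below 0.664 and 5% above 2.19.

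**Figure D1:**
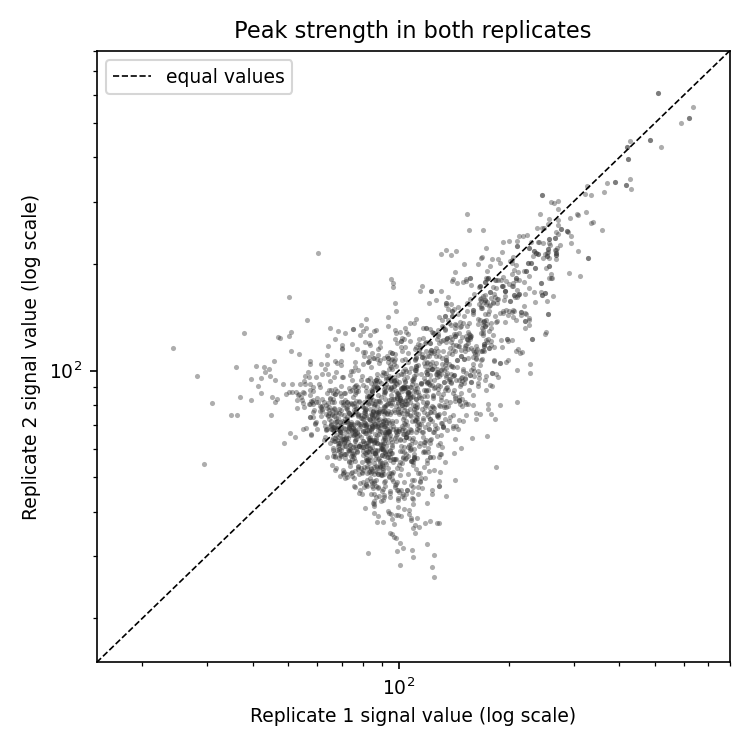
Authors' signal value of each of 1938 IDR peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per peak, with equal values on the dashed line. Values are those of the strongest overlapping peak in each replicate's list, so some IDR peaks share the same point. Pearson r was 0.849 and Spearman rho 0.571, neither of which measures closeness to the line. The median ratio of replicate 1 to replicate 2 was 1.22, so most points lie on the replicate 1 side of the line. The points spread widely at low values.

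The replicates' lists differed in which strong peaks of the other they lacked. Among the 2137 strongest peaks of replicate 2, 388 (18.2%) overlapped no peak anywhere in replicate 1's list, whereas the reverse held for 87 (4.07%). The strongest of the 388 was the fourth peak of replicate 2, on chromosome III at 8043811 to 8044137, with a signal value of 501. No gene starts within 500 bp of it, and K12H4.5 is the nearest. The next were at the snoRNA gene ZK994.7 (361), at the tRNA gene F17H10.t1 with the non-coding F17H10.8 (330), at the snoRNA gene H09I01.2 with the non-coding H09I01.4 (285), and at the snoRNA gene C41C4.11 with chst-1, C41C4.9 and C41C4.15 (264). The pooled signal values at these 5 peaks were 865, 784, 755, 82.9 and 530 in that order, so for all but the peak at H09I01.2 the pooled value was well above that of replicate 2, and their absence from replicate 1's list does not show that replicate 1 lacked signal there. The 5 strongest peaks of replicate 1 that overlap none in replicate 2's list were weaker, at 105 to 115 (pooled values 62.8 to 149). They lay nearest to pat-3, within 500 bp of the 5' ends of T09B4.5 and T09B4.21, at T28B8.1, nearest to duo-3, and at the non-coding genes C46C2.11 and C46C2.12. Of the 388 peaks, 151 were on X and 163 were also absent from the pooled list.

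The strongest HMG-4-eGFP peaks lay at genes for small non-coding RNAs. Of the 25 strongest IDR peaks, 20 had the 5' end of a tRNA, small nucleolar RNA (snoRNA), small nuclear RNA (snRNA) or microRNA gene within 500 bp, with 12 at snoRNA genes, 5 at tRNA genes, 2 at microRNA genes and 1 at an snRNA gene. The strongest of all was on chromosome V at 12303420 to 12303851, at the snoRNA genes C51F7.3 and C51F7.4, which lie within the protein-coding gene frm-7. Its signal value was 1189 in the pooled list, 634 in replicate 1 and 555 in replicate 2. It was followed by the snoRNA gene W03C9.9 on chromosome II at 11960651 to 11961101 (pooled signal value 1142), by the microRNA gene mir-52, beside a pair of unclassified non-coding genes, on chromosome IV at 14033632 to 14034553 (1112), by mir-51 with F36H1.17 on chromosome IV at 11025789 to 11026415 (1086), and by the leucine tRNA gene C04A11.t1 on X at 13665402 to 13665799 (950). The other snoRNA genes at these peaks were T03F7.8, ZK265.10, T02E1.9, ZK994.7, T06C12.16, C04G6.12, Y43F8C.22, Y38F2AR.14, ZK484.9 and Y23H5B.10, several with unclassified non-coding genes beside them (T03F7.14, ZK484.10 and Y23H5B.13). The other tRNA genes were F17H10.t1 for glycine, F41D9.t3 for asparagine, C37A2.t1 for cysteine, which lies within cye-1, and F57F5.t1 for isoleucine, which shares its peak with gcy-33 and F57F5.7. The snRNA gene was R07E5.16. Peak 14, on chromosome I at 13463774 to 13464331, was at rpr-1, the RNA of RNase P, and peak 24, on chromosome II at 7200097 to 7200494, was at mrpr-1, the RNA of RNase MRP, with pcrg-1. T13C5.6 with C14F11.14, T02E1.2 and atx-2, the worm ataxin-2 gene, were also within 500 bp of a summit among the 25, and the eighth peak, nearest to K12H4.5, whose 5' end is 508 bp away, had no gene within that distance. All 25 were in replicate 2's list, none below rank 47, and 22 were in replicate 1's, none below rank 25.

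Over all IDR peaks, 188 summits lay within 500 bp of the 5' end of a tRNA gene, 14.2 times the mean of 1000 circular shifts (13.2). Summits were also more frequent at snoRNA genes (88 summits, 12.5 times), snRNA genes (25, 11.99 times), microRNA genes (28, 5.28 times) and other non-coding RNA genes (597, 4.34 times), and less frequent at piRNA genes (28, 0.389 times). Each of these had a two-sided permutation p of 0.002, the smallest that 1000 shifts can give. The median signal value was 251 at the 327 peaks with any tRNA, snoRNA, snRNA, microRNA or rRNA gene within 500 bp and 169 at the rest. At tRNA genes the median summit lay 35.5 bp inside the gene, and at protein-coding genes it lay 150.5 bp upstream of the annotated 5' end.

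Lists of genes fixed beforehand showed which kinds of gene carried a summit within 500 bp of the 5' end. Of 19973 protein-coding genes, 874 (4.38%) did. Cytosolic ribosomal protein genes had the highest share of the protein-coding lists with this window, 33 of 81 members (40.7%, 95% interval 29.9 to 52.2) against 4.23% of other protein-coding genes (two-sided Fisher's exact test, adjusted p = 3.68e-23). With a window of 200 bp the share fell to 7.41% (Fisher adjusted p = 0.0274), below histones (15.3%), muscle markers (13.6%), tubulins and actins (11.8%), transcription elongation and FACT genes (10.7%), epidermis markers (10%), translation factors (9.09%) and the respiratory chain (7.89%), and with the 1068 strongest IDR peaks it was 23.5% against 24.2% for translation factors, so the lead depends on these choices. Examples were rpl-3 (signal value 528), rpl-15 (380), rps-28 (365) and rps-19 (310). Histone genes had a peak in 13 of 72 (18.1%, interval 9.98 to 28.9; Fisher adjusted p = 4.08e-05), among them his-67 and his-68, which share a peak of 468, the linker histone gene his-24 (233) and his-37 (204). Translation factor genes had a peak in 10 of 33 (30.3%, interval 15.6 to 48.7; Fisher adjusted p = 3.21e-06), with eif-3.C (320), eef-1A.2 (308), iff-2 (290) and eif-3.E (197). Heat shock and chaperonin genes followed with 7 of 30 (23.3%, interval 9.93 to 42.3; Fisher adjusted p = 0.000673), led by hsp-1 (330), cct-7 (182), cct-8 (176) and hsp-3 (175). Respiratory chain and ATP synthase genes had 8 of 38 (21.1%, interval 9.55 to 37.3; Fisher adjusted p = 0.000575), with cox-5B (297), cox-5A (204), cyc-1 (185) and cyc-2.1 (175). Tubulin and actin genes had 4 of 17 (23.5%, interval 6.81 to 49.9; Fisher adjusted p = 0.0110), namely tba-7 (441), tba-1 (215), act-4 (145) and tba-2 (141). Cell cycle and DNA replication genes had 6 of 35 (17.1%, interval 6.56 to 33.6; Fisher adjusted p = 0.00805), including the cyclin-dependent kinase inhibitor cki-1 (230), cdk-4 (220) and the replication factor C genes rfc-4 (196) and rfc-1 (158). Muscle markers had 4 of 22 (18.2%, interval 5.19 to 40.3, Fisher adjusted p = 0.0267), the paramyosin gene unc-15 (156), the myosin light chain genes mlc-3 (137) and mlc-2 (134) and the myosin heavy chain gene unc-54 (130). These signal values are pooled, and some differed between replicates. The peak at iff-2 overlapped none in replicate 1's list. Values in replicates 1 and 2 were 123 and 27.9 at act-4, 82.3 and 30.6 at unc-54, and 42.9 and 102 at tba-2. With a window of 200 bp the calls for translation factors, heat shock and chaperonin genes, the respiratory chain, tubulins and actins, and the cell cycle did not pass, with Fisher adjusted p of 0.0794, 0.674, 0.0997, 0.0997 and 0.284, and with shares 4.19, 1.53, 3.63, 5.41 and 2.63 times those of other protein-coding genes (6.99, 5.37, 4.85, 5.40 and 3.94 times with 500 bp). The calls for heat shock and chaperonin genes, the respiratory chain, tubulins and actins, and the cell cycle also ended with the 1068 strongest IDR peaks, at 3.14, 3.72, 5.54 and 4.04 times, so for the last pair the ratio stayed about as large while fewer peaks were counted. The muscle call ended with those peaks, with a 1000-bp window and without replicate 1, where 4.55% of muscle markers had a peak. The cell cycle call also ended without replicate 2 (11.4%, Fisher adjusted p = 0.0796), where translation factors (18.2%, Fisher adjusted p = 0.00390) and the respiratory chain (13.2%, Fisher adjusted p = 0.0293) still passed with lower shares.

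Among the RNA gene classes, 199 of 612 tRNA genes had a summit within 500 bp (32.5%, interval 28.8 to 36.4) against 4.004% of other annotated genes (Fisher adjusted p = 3.68e-115). The share was 24.0% for snoRNA genes (83 of 346, interval 19.6 to 28.8; Fisher adjusted p = 1.48e-36), 16.3% for snRNA genes (21 of 129, interval 10.4 to 23.8; Fisher adjusted p = 8.25e-07), 14.2% for microRNA genes (37 of 261, interval 10.2 to 19.0; Fisher adjusted p = 1.60e-09) and 20% for spliced leader RNA genes (6 of 30, interval 7.71 to 38.6; Fisher adjusted p = 0.00412). Spliced leader genes with strong peaks were sls-2.4 (521), sls-2.1 (455), sls-2.2 (338) and sls-2.9 (326), and the snRNA gene sup-39 had a peak of 397. The snRNA and spliced leader lists share members, among them sls-2.4 and sls-2.1, so their calls are not independent. The microRNA genes mir-55 and mir-56 shared a peak of 368. Counting microRNA genes within 2 kb as 1 locus ended their call (10.7% against 7.08%, Fisher adjusted p = 0.0761).

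Some lists had peaks less often than other genes. Chemoreceptor genes, most of which are used in sensory neurons, had them in 8 of 1364 (0.587%, interval 0.254 to 1.15; Fisher adjusted p = 3.10e-17), including sri-5 (320), srh-16 (226) and srh-269 (214). C-type lectin genes had 2 of 240 (0.833%, interval 0.101 to 2.98; Fisher adjusted p = 0.00805), clec-126 (377) and clec-140 (147), a call that ended with the 1068 strongest peaks (adjusted p = 0.146 by the same test) and against circular shifts (permutation adjusted p = 0.730). Their share was 0.189 times that of other protein-coding genes, and 0.193 times with the strongest peaks, where fewer peaks were counted. Against shifted peaks it was 0.507 times. The piRNA genes had 51 of 15363 (0.332%, interval 0.247 to 0.436, against 6.35% of other annotated genes, Fisher adjusted p = 1.42e-274), of which 21ur-3424, 21ur-3939, 21ur-5331 and 21ur-9329 shared 1 peak of 412. The 51 genes lay at 28 distinct peaks, and genes that share a peak are not independent in Fisher's test. Against shifted peaks, which keep this clustering, summits at piRNA genes were 0.389 times as many, a smaller deficit. Without replicate 1 the piRNA share was 0.709%, still below other genes (Fisher adjusted p = 3.42e-239). Pseudogenes had 11 of 2128 (0.517%, interval 0.258 to 0.923; Fisher adjusted p = 2.48e-27), the strongest at WBGene00014724 (533).

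The other 15 of the 32 lists did not pass. Transcription elongation and FACT genes had a peak in 4 of 28 (14.3%, interval 4.03 to 32.7; Fisher adjusted p = 0.0571), with values of 156 at spt-16, 155 at rpb-11, 149 at pafo-1 and 146 at cdk-9; in several alternatives, such as a 1000-bp window (Fisher adjusted p = 0.0483) or without replicate 1 (17.9%, Fisher adjusted p = 0.0190), this list did pass. Neuropeptide and insulin genes had 1 of 140 (0.714%, Fisher adjusted p = 0.0571), which passed as lower without replicate 1 (Fisher adjusted p = 0.0278), with gene bodies counted (Fisher adjusted p = 0.00337), with genes within 2 kb merged (Fisher adjusted p = 0.0415) and without peaks at small RNA genes (Fisher adjusted p = 0.0176). No peak was found at 33 proteasome genes, 34 early zygotic lineage regulators, 41 maternal and germline genes, 31 major sperm protein genes, 6 vitellogenin genes, 74 cytochrome P450 genes, 20 intestine markers or 20 rRNA genes, which allows shares, at 3 counts of the total, of up to 9.09% for proteasome genes, 8.82% for lineage regulators, 7.32% for maternal and germline genes, 9.68% for major sperm proteins, 50% for vitellogenins, 4.05% for cytochromes P450 and 15% each for intestine markers and rRNA genes; exact 95% upper bounds ran from 4.86% for cytochromes P450 to 45.9% for vitellogenins. Peaks did appear in a single replicate's strongest peaks at 9.09% of proteasome genes (without replicate 1), 2.44% of maternal and germline genes (without replicate 1) and 2.94% of lineage regulators (without either replicate). Cytochromes P450 passed as lower with a 1000-bp window (Fisher adjusted p = 0.0271) and with gene bodies counted (Fisher adjusted p = 0.0262). Mitochondrial ribosomal proteins had 3 of 70 (4.29%), collagens 4 of 156 (2.56%), neuron markers 1 of 26 (3.85%), epidermis markers 2 of 20 (10%) and long non-coding RNAs 7 of 194 (3.61%). Of these, mitochondrial ribosomal proteins had 8.57% without replicate 1, and without replicate 2 collagens had 3.85%, neuron markers 7.69%, epidermis markers 5% and transcription elongation and FACT genes 7.14%, none of them past the threshold.

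**Figure D2:**
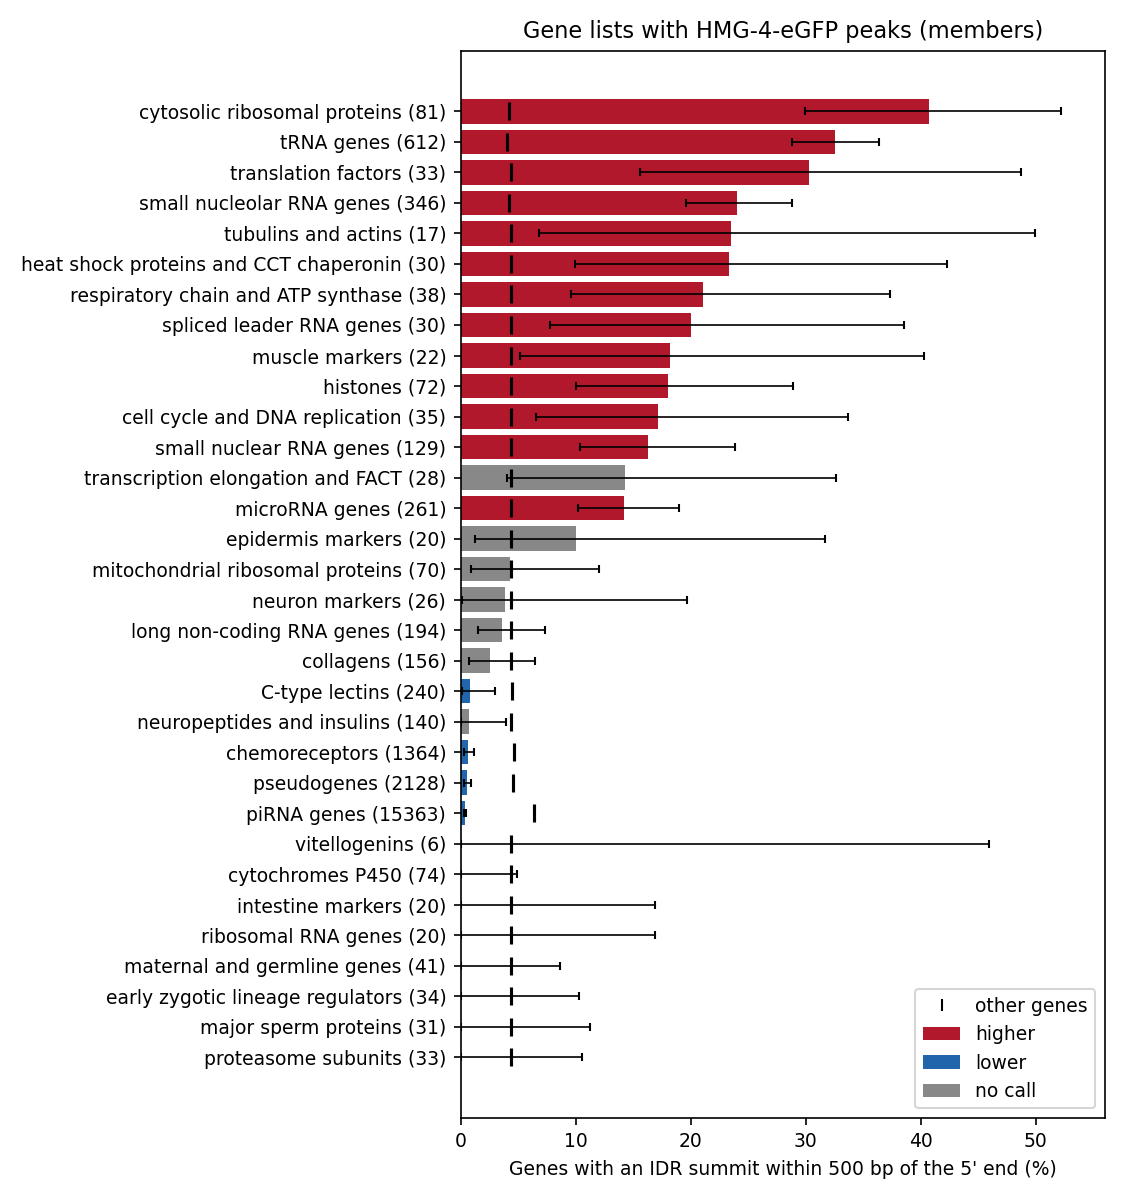
Share of each gene list's members with an IDR summit within 500 bp of the 5' end (bars, %, x axis), with exact 95% binomial intervals and, as a tick, the share of the other genes. Cytosolic ribosomal protein genes (40.7%) and tRNA genes (32.5%) had the highest shares, and piRNA genes the lowest of the lists with any peak (0.332%).

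By annotation, 1341 IDR summits (62.8%, interval 60.7 to 64.8) lay within 500 bp of the 5' end of a gene, against 28.3% of circularly shifted summits. Coding exons held 59 summits (2.76% against 18.05%), introns 258 (12.1% against 27.4%), UTR exons 15 (0.702% against 2.97%), non-coding RNA exons 8 (0.374% against 1.22%) and the 500 bp downstream of genes 46 (2.15% against 4.02%). Each of these 6 classes had an adjusted permutation p of 0.0023. Intergenic sequence elsewhere held 410 (19.2% against 18.1%), with an adjusted permutation p of 0.260, which passed with a 200-bp window (1.25 times, permutation adjusted p = 0.0028). Without replicate 2, coding exons held 5.62%, or 0.310 times the shifted share. With the 5' ends of protein-coding genes alone, an alternative chosen after seeing the data, 750 summits (35.1%) were at gene starts against 17.96% of shifted ones. The 500 bp downstream of genes then did not differ past the threshold (6.88% against 6.90%, permutation adjusted p = 0.999), non-coding RNA exons held more summits (5.01 times) and intergenic sequence passed as higher (1.12 times, permutation adjusted p = 0.0257). Within protein-coding genes of at least 1 kb, summits were less frequent than in shifts in each of 5 equal parts of the gene body, from 0.786 times in the part at the 5' end to 0.308 times in the part at the 3' end (adjusted permutation p = 0.002 for each). Peaks at gene starts were stronger than the others, with a median signal value of 181 against 165 and a median rank of 985 against 1226.5 (two-sided permutation test, p = 1e-05, the smallest it can give). This was not seen at the starts of protein-coding genes alone, where the median was 174 against 177 for the rest (permutation p = 0.470 for the difference in median rank). The 200 bp around summits had a mean GC content of 48.9% ± 5.88 (SD over 2137 peaks), against 35.5% in shifted sets, none of which exceeded 36.001% (permutation p = 0.002). GC content also biases libraries of this kind, and the shifts cannot separate such a bias from a property of the sites.

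**Figure D3:**
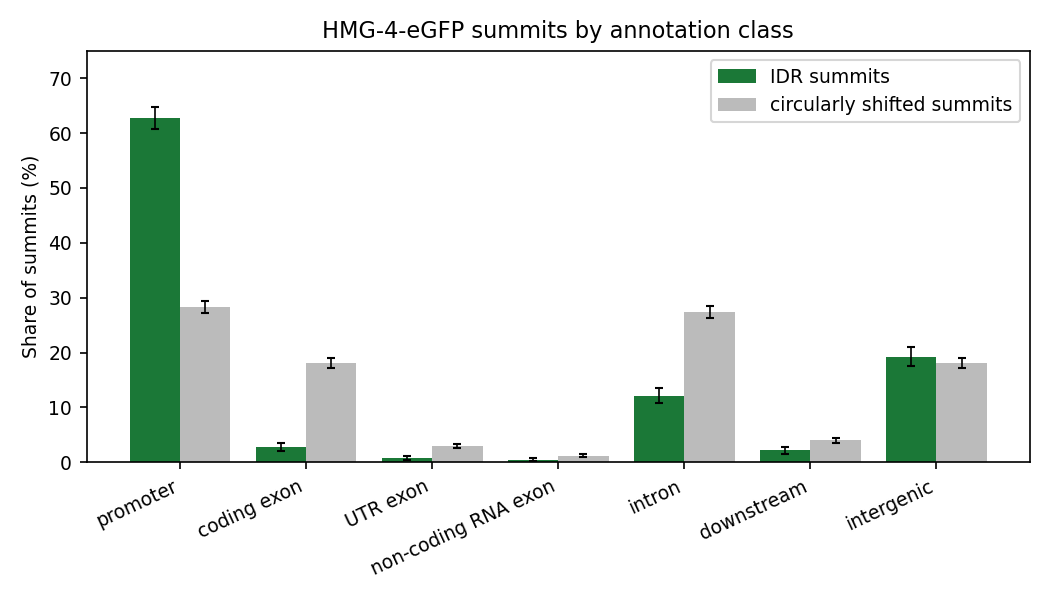
Share of 2137 IDR summits in each annotation class (green bars, %, with exact 95% binomial intervals) and of summits shifted along the chromosomes (grey bars, mean ± SD of 1000 shifts). Gene starts held 62.8% of summits against 28.3% of shifted ones, and coding exons 2.76% against 18.05%.

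The X chromosome held 592 of the 2137 IDR peaks (27.7%, interval 25.8 to 29.7), against 17.7% of the genome's length (exact binomial test, adjusted p = 8.70e-30). Chromosome I (19.1% against 15.03%, binomial adjusted p = 3.86e-07) and chromosome III (16% against 13.7%, binomial adjusted p = 0.00340) also held more, chromosome IV (11.3% against 17.4%, binomial adjusted p = 5.80e-15) and chromosome V (11.1% against 20.9%, binomial adjusted p = 4.77e-32) fewer, and chromosome II did not differ past the threshold (14.8% against 15.2%, binomial adjusted p = 0.588). The chromosome III call ended with the 1068 strongest peaks (14.98%, binomial adjusted p = 0.297), and chromosome II passed against the distribution of protein-coding 5' ends (binomial adjusted p = 0.00219). The X share varied with the number of pooled peaks taken, from 30% among the 100 strongest to a maximum of 37% among the 500 strongest and 14.96% among all 30000. Replicate 1 (24.8% of its 2137 strongest) and replicate 2 (28.2%) both showed the excess. On the autosomes, 905 of 1545 peaks (58.6%, interval 56.1 to 61.0) were in the central 50% of the chromosome (two-sided permutation p = 0.006 against shifts). Of the autosomal protein-coding genes, 55.7% start there, and the peaks were not tested against that share. On X, 302 of 592 peaks (51.01%, interval 46.9 to 55.1) were in the central 50%.

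**Figure D4:**
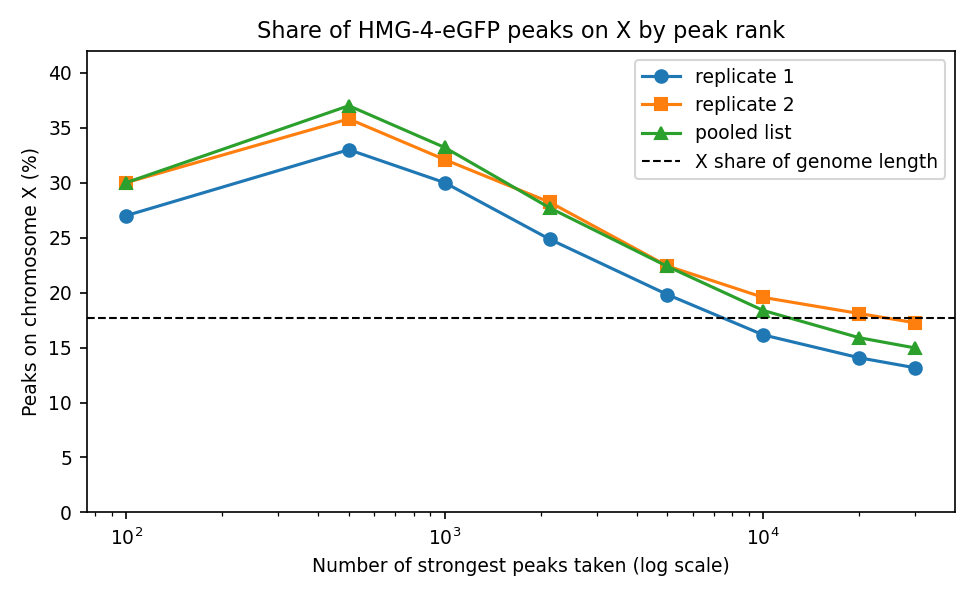
Share of peaks on X (y axis, %) among the strongest peaks of each list (x axis, number of peaks taken, log scale), with the X share of the genome's length (17.7%) as a dashed line. In the pooled list the share was 37% for the top 500 and 14.96% for all 30000.

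The transgene holds hmg-4 and an unc-119 rescue marker, so both places were examined for signal from copy number. Within 20 kb of hmg-4 (chromosome III, 7379143 to 7381596, minus strand) there were 6 IDR peaks, a number that 0.770% of 10000 windows of this size centred on protein-coding genes reached. The strongest, at 7376154 to 7376593 with a signal value of 301, was intergenic and nearest to T20B12.7. Of the other peaks, that with its summit at 7376579 was also intergenic and overlapped the strongest. Those with summits at 7378299 and 7378528 were in coding exons of T20B12.7 and overlapped each other. That at 7383453 was in a coding exon of T20B12.3 and that at 7382190 was at the start of T20B12.3. The 6 peaks are therefore not 6 separate sites. None lay within 500 bp of the 5' end of hmg-4 itself. In the full pooled list the window held 10 peaks, which 56.2% of windows reached. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935) there was no IDR peak, and 28 pooled peaks, which 7.24% of windows reached. The paralog hmg-3 (chromosome I, 5815609 to 5818132) had no peak within 500 bp of its 5' end, and 1 IDR peak within 20 kb, at vps-51 and lin-35 (221). The gene for the other FACT subunit, spt-16 (chromosome I, 10789130 to 10793152), had a peak at 10788631 to 10789070, with its summit 279 bp upstream of the 5' end.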

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

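Alternatives named here as chosen after seeing the data were 5' ends of protein-coding genes alone, IDR peaks present in both replicates' lists, peaks away from small RNA genes, chemoreceptors by named families, hmg-4 left out of its list and, for peak strength, each replicate left out; the others were planned. The share of strong peaks in both replicates stayed above the shifted sets under all 4 alternatives (48.2% to 62.9%). The correlation of signal values was 0.819 (Spearman 0.539) with summits matched within 100 bp, and its Spearman value was 0.478 over all pooled peaks; the cause was not tested. The X excess, the excess at gene starts and the GC content kept their direction and their side of the threshold under every alternative run, with X shares of 24.8% to 32.5%. No alternative addressed a GC bias of the libraries. Without each replicate in turn, the X share was 24.8% to 28.2% and the share at gene starts 58.5% to 66.6%. The median rank of peaks at gene starts minus that of the others (negative is stronger) was -318.5 to -272.5 without each replicate in turn and -105.5 away from small RNA genes (permutation p = 0.0126), but turned to 35.5 at the 5' ends of protein-coding genes alone (permutation p = 0.470). The top 2137 of the pooled list is the IDR list itself and tests nothing. The number of gene lists with more peaks than other genes, 13, fell to 8 with a 200-bp window and to 8 with the 1068 strongest peaks, which leave fewer peaks to count. The 13 include the snRNA and spliced leader lists, which share members. Muscle markers turned from more to fewer peaks than other genes with the strongest peaks (0%) and without replicate 1 (4.55% against 4.83%; 18.2% without replicate 2), in neither case past the threshold; the cause was not tested. Non-coding RNA exons turned from fewer to more summits than in shifts (14.5%, 5.01 times) when gene starts were those of protein-coding genes alone, because summits at RNA gene starts then count as exons. Without peaks at small RNA genes, 9 of the 26 lists that could still be tested were higher (8 before) and 5 lower (4 before). Of the values for single lists, chromosomes and classes, counted without the top 2137 of the pooled list, 368 kept their side of the threshold, 16 no longer passed it, 14 newly did, and 3, those of muscle markers and non-coding RNA exons above, turned direction, of which the muscle ones also no longer passed. Depth is unknown, and the 30000-peak limit sets what the lists can show of weak sites. No paired analysis was possible because there is 1 group.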

Other observations

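The tests below, except that of single-copy tRNA genes, were chosen only after the results were seen. Beyond the lists fixed beforehand, all 240 protein-coding gene families with a shared symbol prefix and at least 8 members were tested for a summit within 500 bp of the 5' end (two-sided Fisher's exact test, adjusted over the 240), and 9 passed, all with more peaks. Besides rpl, rps, his, cct, eif and cdk genes, which overlap the fixed lists, they were the sec genes of the secretory pathway (7 of 19, 36.8% against 4.34%, Fisher adjusted p = 0.000762) and the lin (9 of 47, Fisher adjusted p = 0.00766) and unc (13 of 94, Fisher adjusted p = 0.00766) genes, which share a mutant phenotype and not a function. The sec genes were sec-15 (559), sec-61.G (275), sec-61.B (215), sec-16A.2 (215), sec-61.A (193), sec-3 (184) and sec-22 (174), of which sec-61.A, sec-61.B and sec-61.G encode the subunits of the translocon of the endoplasmic reticulum. Peaks at tRNA genes were spread over all amino acids, from 23.6% of glycine tRNA genes (13 of 55) to 47.1% of alanine tRNA genes (16 of 34), with the 1 selenocysteine tRNA gene also at a peak and none of the 5 without a named product.

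Short sequences distinguished summits from their surroundings. Over the 1810 IDR peaks away from small RNA genes, 18218 sequences of 8 bases were compared between the 200 bp at the summit and windows 1000 bp to either side (Fisher's exact test, adjusted over all of them). GAGACGCA was in 12.6% of summit windows and 1.13% of flanking windows (Fisher adjusted p = 2.18e-67), GAGAGAGA in 15.3% and 2.57% (Fisher adjusted p = 9.71e-61) and ACACACAC in 12.7% and 2.38% (Fisher adjusted p = 1.41e-45), while AAAAATTT was in 2.54% and 15.2% (Fisher adjusted p = 3.48e-51). Because 5947 of the sequences passed and summits are rich in G and C, base composition was not separated from single motifs.

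Strong peaks of replicate 2 that are missing from replicate 1's list were examined further. For weaker enrichment in replicate 1, the signal left after subtracting replicate 2 from the pooled value was compared. At the 225 of the 388 peaks with a pooled peak, its ratio to replicate 2 was 0.822 times that at the other 1749 strong peaks (bootstrap interval 0.763 to 0.882), but 163 have no pooled peak, and counting these as 0 gave 0.171 (interval 0 to 0.288). Signal values also did not add up everywhere, as the pooled value was below that of replicate 2 at 15 of the 225 and at 7 of the 1749. Weaker enrichment therefore stays open. Replicate 1 peaks 1 to 5 kb away from the 388 peaks were 0.315 times as many as around other strong peaks (interval 0.277 to 0.358), below the same ratio of 0.568 for replicate 2's own peaks (interval 0.525 to 0.614). Gaps of over 20 kb between neighbouring summits numbered 994 in replicate 1's list, spanning 43.8 Mb, and 606 in replicate 2's, spanning 20.3 Mb. Replicate 2's list thus also had gaps, but they spanned less. The pooled list had 910, spanning 37.6 Mb, but it was called with replicate 1 included, so its gaps are not separate evidence. Stretches left out of replicate 1's list, and weaker enrichment over such stretches, both stay open. No biological explanation was tested, since the design has 1 group.

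The excess of strong peaks on X was weighed against 3 explanations. X has 45.1% of tRNA genes. Without the 188 peaks at tRNA genes, of which 75 are on X, the X share was 26.5% (interval 24.6 to 28.5), still above the 17.7% of genome length, so these genes do not account for it. X held 14.96% of all pooled peaks (interval 14.6 to 15.4) and 17.3% of replicate 2's (interval 16.8 to 17.7). Neither share was above the 17.7% of genome length. Of the 388 strong replicate 2 peaks missing from replicate 1's list, 151 were on X, so gaps may lower the pooled share. The replicate 2 interval includes 17.7%, and each full list ends at a fixed number of peaks. These shares therefore show no excess in the full lists but cannot decide whether more peaks were called everywhere on X. The sequence TCGCGCAGGGAG, recalled as the motif of sites that recruit the X dosage compensation complex, occurred with up to 1 mismatch within 200 bp of 11 of 510 X summits away from small RNA genes and of 0 of 1300 autosomal ones (Fisher's exact p = 8.22e-07), where shifted X summits gave 0.302 on average and at most 3; with up to 2 mismatches it was 25 of 510 and 25 of 1300. Some X peaks may therefore lie at such sites, but without all 12 X peaks with the motif the X share was 27.3%, so they leave most of the excess open, and no comparison with another tagged protein was made.

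Peaks at tRNA genes could come from reads shared among identical copies. Of the 140 tRNA genes whose sequence occurs once in the genome, 30 (21.4%, interval 14.9 to 29.2) had a peak, above the 4.004% of other annotated genes. This test was set before its result was seen. Peaks were thus not confined to genes with identical copies. Only exact matches over the full gene counted as copies, so near-identical genes could still share reads. A summit within 500 bp can also belong to a neighbouring tRNA gene, so the test cannot decide on shared reads. Genes with several identical copies had peaks more often (169 of 472, 35.8%, Fisher's exact p = 0.00140), and shared reads stay open as an explanation. Whether the same sites would be recovered by precipitation of accessible, highly transcribed DNA whatever the tag cannot be told apart from HMG-4 binding, because 0 samples of any other group, such as worms with no tag, were analysed here. The same limit holds for the peaks at all other places in the genome.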
